A study of Sus scrofa with 6 samples.

How the data were processed

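RNA from pig (Sus scrofa) femoral arteries, sampled ex vivo at the site of puncture, was measured on 6 Agilent 1-colour porcine arrays, 3 of arteries treated with TAG and 3 of arteries treated with Exoseal. Per the labels' protocols, total RNA was amplified, labelled with Cy3 and hybridised to the arrays. Per the file headers, the deposited scanner files hold spot intensity values from Agilent Feature Extraction 11.0.1.1 under its standard 1-colour gene expression protocol. The processed signal among them is an intensity that Feature Extraction had background-subtracted, detrended and floored within each array, with no scaling between arrays. A deposited table of the whole series holds the authors' processed values for 43663 probes. From the values themselves, that deposited table is on a log2 scale and scaled between arrays, since all 6 columns share a median of 3.40. It is neither centred per gene nor a ratio. A shared median does not tell quantile normalisation from median scaling. The Spearman correlation of each column with the processed signal of its own array, across probes, ran from 0.941 to 0.995. The authors' software for that normalisation is not given in the sources used here.

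Samples were grouped by their titles. The title and source name of Exoseal replicate 1 give Exoseal, and its treatment characteristic gives TAG, so it was also left out and also counted as TAG as alternatives. All samples carry the same puncture side in the labels. The description field of all 6 samples speaks of another kind of experiment in another organism and was not used. No pair of arrays held identical values, with median absolute log2 differences between 2 arrays from 0.387 to 1.20.

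Each array held 45220 spots, of which 1417 were controls and were left out. Spots of the same probe were averaged on the log2 scale without spots that carried an outlier flag, and 223 of 43603 probes were left out because all their spots on some array were outliers. No spot was saturated. For each array, log2 of the processed signal minus the array's 75th percentile of it was taken. Under 50% of the probes were detected on each TAG array, so the 75th percentile over the 12887 probes detected on all 6 arrays was added as an alternative after the data were examined, and the scaling fixed beforehand was kept. Probes were named through the unversioned RefSeq accession of the array design, matched to a table of the pig genes of assembly Sscrofa11.1, used for names alone. This gave 1 symbol to 5435 of 43380 probes (2384 symbols), and the other 37945 probes were kept unnamed under their own identity. The genome build behind the array design is not given in the sources used here, so no coordinates are given. For each symbol the probe with the highest mean log2 signal over the 6 arrays stood for the gene, which left 40329 features. Features had to be well above background, by the scanner's flag, on at least 3 of the 6 arrays, and 20857 were tested (1614 named genes and 19243 unnamed probes). Where a probe was not well above background on any array of a group, the difference is given as at least a certain fold, from the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal, and for such genes that did not pass no difference is given at the scaling used. The number of arrays limits the precision of every value.

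The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, TAG minus Exoseal, no covariates), with Benjamini-Hochberg adjustment over all features and a threshold of 0.05. Errors of fold changes are standard errors from limma, and errors of levels are standard deviations over 3 arrays. On data simulated for this comparison with 20857 features and 200 changed ones, the test recovered 1% of changes of 1 log2 unit and 76.2% of changes of 3 log2 units, and called 5.20 unchanged features on average. With no change simulated, it called at most 1 feature. A list of 13 genes lowered by 2 log2 units gave a p of at most 1.65e-22 with camera. The measured foreign body and giant cell list, also of 13 genes, had a median of -1.03 and an estimated correlation between genes of 0.284. So the planted list does not show how camera fares on a measured list like that.

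Before the data were examined, 35 gene lists were fixed, and 24 with at least 5 measured genes were tested with limma's camera at its preset correlation of 0.01, with adjustment over the lists. Camera with an estimated correlation and fry were run beside it. For each list the members past the gene test are counted over all features, and adjusted over the list alone. Genes named in the text follow a rule fixed at the same time: the 12 per direction with the largest absolute fold change among those past the threshold with groups that do not overlap, up to 4 members past the threshold of each list or, with none, the 2 with the smallest p, and 9 reference genes, of which 3 (ACTA2, PECAM1 and ACTA1) were kept by the filter. This named 69 genes, of which 1 is not reported here, nor is the list it belongs to. Some list members outside the rule are given as values to describe a list. The groups' numbers of detected probes were compared with an exact two-sided permutation test, whose smallest possible p with 3 against 3 is 0.1. Alternatives covered background correction, scaling, the authors' table, the filter, the treatment of probes of the same gene, the variance model, array weights, blocks for the replicate number and the slide, and each array left out. The background correction was normexp with an offset of 50, which shrinks the fold changes of dim features. The mean of a gene's probes took in all its probes, also those that did not pass the filter. The headers place the 3 TAG arrays and Exoseal replicate 1 on slide 1, scanned at a detector voltage of 355, and Exoseal replicates 2 and 3 on slide 2, scanned at 287. With slide as a block, or within slide 1, the fold change of a gene is that of the TAG arrays against Exoseal replicate 1, and the spread of that lone Exoseal array is taken from the others. Figures were drawn with matplotlib 3.10.9.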

Results

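Gene expression was measured in pig femoral arteries taken ex vivo at the puncture site after minimally invasive repair. The puncture of 3 arteries had been closed with TAG, a vascular glue, and that of 3 with Exoseal, a marketed closure device that seals the puncture from outside the vessel with a bioabsorbable polyglycolic acid plug. The labels do not say whether the samples of a group came from separate animals, so p-values measure the spread between these samples, which may in part be technical. Exoseal replicate 1 carried both treatments in its labels and was scanned on the same slide as the 3 TAG arrays, and Exoseal replicates 2 and 3 shared a second slide.

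The TAG arrays detected fewer probes than the Exoseal arrays. On average 37.4% ± 3.38 (SD, n = 3) of probes were well above background on TAG arrays and 64.3% ± 5.70 (SD, n = 3) on Exoseal arrays, with 60.6% on Exoseal replicate 1. The exact two-sided permutation test gave p = 0.1, the smallest this design allows. The 75th percentile of the processed signal ran from 19.3 to 36.4 on TAG arrays and from 61.0 to 151 on Exoseal arrays. Negative controls averaged 18.0 to 30.9 on slide 1, and 1.82 and 1.63 on slide 2. Across the tested features, which are not independent replicates, Pearson's r between arrays was 0.944 to 0.956 within TAG, 0.789 to 0.936 within Exoseal and 0.729 to 0.855 between the groups. The first principal component held 59.7% of the variance and the second 21.1%.

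**Figure D1:**
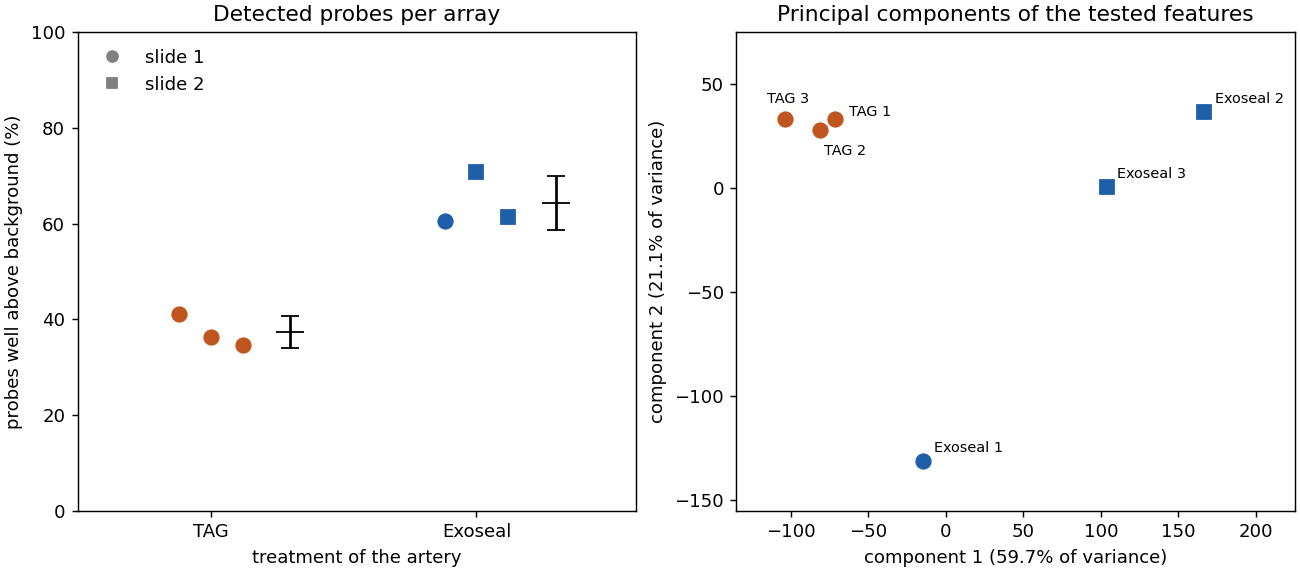
Left, percent of probes well above background on each array (y axis) by treatment (x axis), with the mean and SD of 3 arrays in black. Right, position of each array on the first 2 principal components of the tested features. Circles are arrays of slide 1 and squares arrays of slide 2, and Exoseal replicate 1 lies apart from Exoseal replicates 2 and 3 on both components.

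The comparison of TAG with Exoseal asks how the transcripts of the artery at the puncture site differ between the glue and the device. Genes that fell in TAG included ACP5 (tartrate-resistant acid phosphatase of osteoclasts and macrophages), CCR1 (a chemokine receptor of leukocytes), LYZ (lysozyme) and MMP9 (gelatinase B), by 32.1-fold, 22.9-fold, 12.5-fold and 5.99-fold by the brightest probe of each (n = 3 arrays per group). Genes that rose included ACTA2 (smooth muscle actin) by 4.66-fold and DES (desmin) by 2.86-fold, 2 of 7 contractile genes, COL5A1 (a fibrillar collagen chain) by 9.49-fold and SPARC (osteonectin) by 4.02-fold, 2 of 5 matrix genes of which 3 rose, and the heat shock genes HSP70.2, HSPA6 and HSPB1 by 8.60-fold, 6.07-fold and 5.11-fold. As the mean of their probes ACP5, MMP9, COL5A1 and DES did not pass (log2 fold changes -0.93, -1.40, 2.26 and 1.83). With quantile scaling COL5A1, SPARC, DES and HSPB1 did not pass (1.86, 1.48, 0.75 and 0.38), nor with median scaling ACTA2, DES, SPARC, HSPA6 and HSPB1 (1.76, 1.06, 1.54, 2.14 and 1.89). Within slide 1, against Exoseal replicate 1 alone, ACTA2 had 1.89, DES 1.50, COL5A1 2.33, SPARC 1.42, HSP70.2 2.24, HSPA6 2.73 and HSPB1 2.08. There ACP5 had -5.92, CCR1 -4.86, LYZ -3.11 and MMP9 -3.17. In the lists 3 of 8 macrophage genes and 3 of 13 giant cell genes fell, and 4 of 14 immediate early and heat shock genes rose. Leaving out any TAG array, or Exoseal replicate 2 or 3, left 0 features past the threshold. No gene list as a whole passed its test.

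Of 20857 features tested, 2139 passed an adjusted p of 0.05 in limma (10.3%), with 1374 higher and 765 lower in TAG. Among 1614 named genes, 90 rose and 49 fell. The smallest adjusted p was 0.0178, and 6251 features had an unadjusted p under 0.05 with at least a 2-fold difference. The groups did not overlap for 35.7% of features, against 10% by chance. Of the features that passed, 1024 were above background on all 6 arrays (of 11702 such features tested), 805 of them higher and 219 lower in TAG. Another 399 were not above background on any TAG array, of 3888 such features tested, and 37 not on any Exoseal array, of 37 tested. Such features passed the filter only by being above background on all 3 arrays of the other group. These counts are therefore no separate result. The median log2 difference of all features was 0.03 and moved to -0.08 with quantile scaling, -0.43 with median scaling and 0.17 with the percentile of probes detected on all arrays. The share of calls higher in TAG was 64.2%, and became 49.1% with quantile scaling (1361 higher, 1413 lower) and 46.0% with median scaling (508 higher, 597 lower). With slide as a block 1849 features passed (982 higher, 867 lower), and within slide 1, which rests on Exoseal replicate 1 alone, 2386 passed (1267 higher, 1119 lower). Leaving out Exoseal replicate 1 gave 6957 calls. Leaving out TAG replicate 1, 2 or 3 or Exoseal replicate 2 or 3 gave 0 each in limma, with 4720, 4707, 4081, 5526 and 4946 features at an unadjusted p under 0.05 and at least 2-fold. Without the filter on dim features, 0 of 40329 passed, with 13158 at an unadjusted p under 0.05 and at least 2-fold.

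Among the 12 named genes that fell most in TAG, ACP5 had a log2 fold change of -5.00 ± 0.59 (adjusted p = 0.0178), CCR1 -4.52 ± 0.53 (0.0178), F5 (coagulation factor V) -3.73 ± 0.50 (0.0206), LYZ -3.64 ± 0.66 (0.0229) and HMOX1 (haem oxygenase 1) -3.60 ± 0.55 (0.0206). C14H10orf128, an open reading frame of unassigned function, had -4.49 ± 0.80 and GALNS, a lysosomal sulfatase, -2.96 ± 0.59. F5 and GALNS were above background on 2 of 3 TAG arrays and C14H10orf128 on 1 of 3. Another 5 of these genes were not well above background on any TAG array: PIK3R5 (a regulatory subunit of PI3-kinase gamma) was at least 3.24-fold lower in TAG, ARG1 (arginase 1) at least 3.51-fold, RAD18 (a ubiquitin ligase of DNA damage tolerance) at least 2.68-fold, NEU1 (lysosomal sialidase) at least 4.48-fold and FLVCR2 (a membrane transporter) at least 4.81-fold, at the scaling used. With normexp and quantile scaling the fitted log2 fold changes of these 5 lay below their bounds in size, from -1.20 (NEU1) to -0.85 (RAD18), and NEU1 had -1.85 within slide 1. The offset of 50 in normexp shrinks the fold changes of such dim genes. Within slide 1 the fitted log2 fold change was -5.92 for ACP5, -4.86 for CCR1, -3.10 for F5, -3.11 for LYZ, -3.03 for HMOX1, -3.44 for C14H10orf128 and -1.81 for GALNS. Of other probes passing the filter, 1 of 3 for ACP5, 0 of 1 for HMOX1 and 1 of 2 for GALNS kept the sign. The rest went the other way and reached 1.28, 1.21 and 1.89, while the GALNS probe of the same sign had -3.94. The fold changes given are those of the brightest probe. As the mean of their probes ACP5 (-0.93), HMOX1 (-0.71), C14H10orf128 (-1.02), GALNS, ARG1 and FLVCR2 did not pass, but no other probe of FLVCR2 passed the filter. The TAG arrays detected fewer probes overall (37.4% against 64.3%).

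In the lists of infiltrating cells, every gene that passed the test over all features had fallen in TAG. Of 8 measured macrophage and monocyte genes, 3 fell (3 also adjusted over the list alone): LYZ, CD86 (a costimulatory ligand, -1.92 ± 0.52, above background on 1 of 3 TAG arrays) and AIF1 (a calcium-binding protein of macrophages, -1.80 ± 0.45). As the mean of their probes CD86 (0.0140) and AIF1 (-1.60) did not pass, but no other probe of CD86 passed the filter. The other macrophage genes did not pass, with C1QA at 0.68, CD163 at 0.10, FCER1G at -0.43 and CD14 at 0.23 (above background on 1 of 3 TAG arrays, and -1.54 within slide 1), and TYROBP not well above background on any TAG array. In the list of foreign body and multinucleated giant cells, 3 of 13 fell (ACP5, MMP9 at -2.58 ± 0.50 and SPP1, osteopontin, at -2.08 ± 0.55), and adjusted over the list alone 5 fell and 1 rose. The other probe of MMP9 had -0.23. On slide 1 alone MMP9 had -3.17, SPP1 -1.09, CD86 -2.91 and AIF1 -2.10, and with slide as a block SPP1 did not pass. The list's median log2 difference was -1.03, and -1.22 within slide 1. CTSK, the collagen-degrading protease of osteoclasts, had 1.39 (adjusted p = 0.0661). Of 4 neutrophil genes, ARG1 and MMP9 fell (adjusted over the list alone 2 fell and 1 rose), and S100A12 had 1.72 (adjusted p = 0.0793). None of 8 T and NK cell genes passed, with CD8A at 1.05 and GZMB not well above background on any TAG array, nor did any of 3 mast cell and eosinophil genes (GATA2 -0.62, KIT -0.36), and adjusted over the list alone 0 passed in either. No B cell or plasma cell gene was kept by the filter. Median log2 differences were -0.31 for macrophages (-1.42 within slide 1), -1.10 for neutrophils (-1.31), -0.32 for T and NK cells (-0.90) and -0.36 for mast cells and eosinophils (-0.96). Fewer probes were detected on TAG arrays, which touches each of these lists. The dimmest 20% of all features had a median log2 difference of 0.09, and -0.76 within slide 1. Falls of list medians within slide 1, here and below, may thus in part be shared with dim features of any kind.

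In the inflammation lists few members passed. CXCL10, an interferon-induced chemokine, fell by 1.90 ± 0.49 on the log2 scale and was the only 1 of 13 chemokines past the test, and adjusted over the list alone 3 fell and 1 rose. ISG15, an interferon-induced ubiquitin-like protein, rose by 1.77 ± 0.44, as 1 of 13 interferon response genes (2 rose and 1 fell adjusted over the list alone). C3, the central component of complement, rose by 2.05 ± 0.47 as 1 of 13 complement genes (1 adjusted over the list alone). CD86 was the 1 of 13 antigen presentation genes that fell, and 0 passed adjusted over the list alone. ITGB2, the beta chain of the leukocyte integrins, fell by 1.89 ± 0.52 (above background on 2 of 3 TAG arrays) and ANGPT2 (angiopoietin 2) by 1.70 ± 0.44, as 2 of 7 endothelial activation and adhesion genes (2 adjusted over the list alone). As the mean of their probes CXCL10 (-1.78), C3 (1.40) and ITGB2 (-1.89) did not pass, nor with median scaling C3 (1.59), ISG15 (1.30), ITGB2 (-2.36) and ANGPT2 (-2.16). On slide 1 alone CXCL10 had -1.88, ISG15 1.59, C3 1.42, ITGB2 -1.81 and ANGPT2 -1.57, and with slide as a block none of these 5 passed. None of 12 inflammatory cytokine genes passed, over all features or adjusted over the list alone (IL18 -1.39, NFKBIA 1.45), and none of 11 lysosome and phagocytosis genes (NPC2 1.44, ATP6V1A 0.74). Median log2 differences, with those within slide 1 in parentheses, were -0.41 (-1.05) for chemokines, 0.03 (-0.04) for interferon response, 0.68 (0.52) for complement, -0.31 (-0.40) for antigen presentation, 0.13 (0.15) for endothelial activation, -0.62 (-1.07) for cytokines and 0.50 (0.43) for lysosome genes. For the dimmest 20% of all features they were 0.09 (-0.76).

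**Figure D2:**
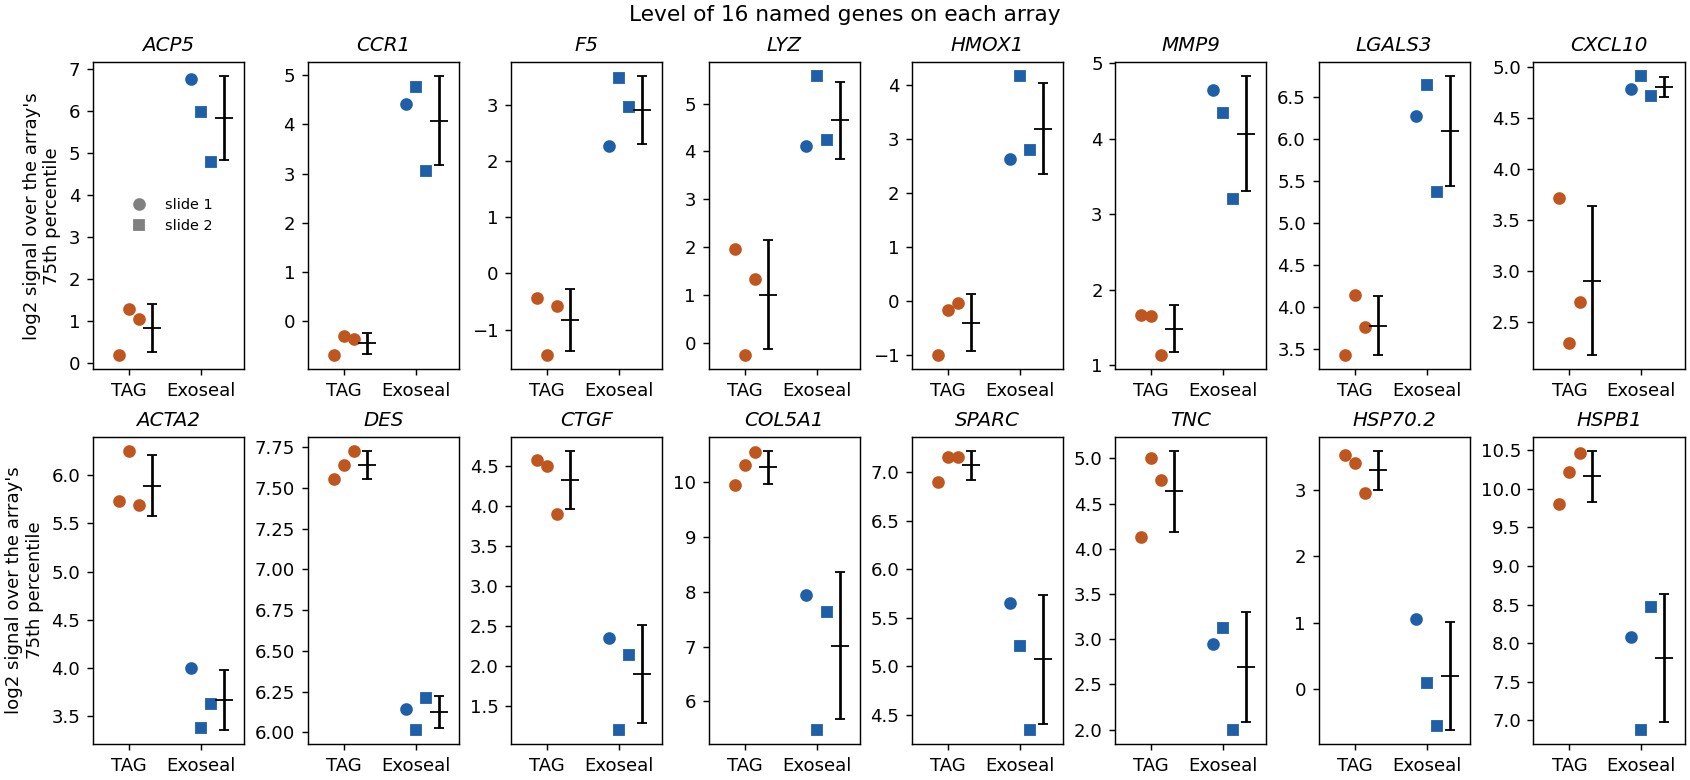
Level of 16 named genes on each array, as log2 of the signal over the array's 75th percentile (y axis, a scale of its own in each panel that need not start at 0) by treatment (x axis). Points are single arrays, circles of slide 1 and squares of slide 2, and black bars are the mean and SD of 3 arrays. The level of ACP5 was 0.84 ± 0.58 in TAG and 5.84 ± 1.00 in Exoseal, and that of ACTA2 5.89 ± 0.32 and 3.67 ± 0.31.

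In the lists of the artery wall and of matrix, genes that passed went both ways. In the contractile smooth muscle list ACTA2 rose by 2.22 ± 0.43 (adjusted p = 0.0242) and DES by 1.52 ± 0.40 (0.0447), 2 of 7 members (2 adjusted over the list alone), and MYLK, myosin light chain kinase, had -1.37 (adjusted p = 0.139). In the fibrillar collagen and matrix list 3 of 5 rose, COL5A1 by 3.25 ± 0.65, SPARC by 2.01 ± 0.47 and TNC (tenascin C) by 1.94 ± 0.49, and adjusted over the list alone 3 rose and 1 fell. FBN1 (fibrillin 1), the single elastic fibre gene measured, rose by 1.70 ± 0.43 (1 adjusted over the list alone). IGFBP6 rose by 1.45 ± 0.40 as 1 of 2 fibroblast genes (1 adjusted over the list alone), and CTGF (connective tissue growth factor) by 2.42 ± 0.48 as 1 of 10 TGF-beta signalling and target genes (1 adjusted over the list alone). MMP9 was the 1 of 10 matrix proteases and inhibitors that fell (adjusted over the list alone 2 rose and 1 fell). In the list for the phenotypic switch of smooth muscle KLF4, a transcription factor, rose by 2.50 ± 0.52, and LGALS3 (galectin 3) fell by 2.31 ± 0.49 together with SPP1, as 3 of 8 members (3 adjusted over the list alone). Among endothelial genes CDH5 (VE-cadherin) fell by 2.47 ± 0.56 as 1 of 3 (1 adjusted over the list alone), and PECAM1 had -1.57 ± 0.70 (adjusted p = 0.164), or 0.743 as the mean of its probes. The pericyte gene RGS5 had 0.81 and did not pass over all features or adjusted over the list alone. ANGPT2 was the 1 of 3 angiogenesis growth factors that fell (1 adjusted over the list alone). With quantile scaling COL5A1 (1.86), SPARC (1.48), DES (0.75) and IGFBP6 (1.24) did not pass, and with median scaling ACTA2 (1.76), DES, SPARC, TNC (1.48), FBN1 (1.24), IGFBP6 (0.99), CDH5 (-2.93) and SPP1 (-2.54). As the mean of their probes COL5A1 (2.26), DES (1.83), IGFBP6 (1.88) and CDH5 (-1.07) did not pass, but no other probe of CDH5 passed the filter. Within slide 1 the log2 fold change was 1.89 for ACTA2, 1.50 for DES, 2.33 for COL5A1, 1.42 for SPARC, 1.68 for TNC, 1.64 for FBN1, 1.97 for CTGF, 1.42 for IGFBP6, -2.49 for LGALS3 and -1.49 for CDH5, and with slide as a block LGALS3 alone of these passed. Median log2 differences, with those within slide 1 in parentheses, were 0.73 (0.64) for smooth muscle, 1.94 (1.42) for fibrillar collagen, 1.70 (1.64) for elastic fibre, 1.18 (1.05) for fibroblasts, 0.81 (1.29) for pericytes, -0.42 (-0.14) for TGF-beta, -0.44 (-0.44) for matrix proteases, -0.26 (-1.12) for the phenotypic switch, -1.57 (-0.51) for endothelial cells and -0.98 (-1.48) for angiogenesis.

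In the list of immediate early and heat shock genes 4 of 14 rose (4 adjusted over the list alone): HSP70.2 by 3.10 ± 0.51, HSPA6 by 2.60 ± 0.60, KLF4, and HSPB1 by 2.35 ± 0.52. HSPB1 had 0.38 with quantile scaling and 0.42 in the authors' table and did not pass in either, nor did HSPB1 (1.89) and HSPA6 (2.14) with median scaling. The heat shock genes HSPH1 and HSP90AA1 did not pass, with -0.95 and 0.77, nor did the immediate early genes NR4A3 and JUN, with 1.42 and 0.10, and FOS and EGR2, which were not well above background on any TAG array. HSP70.2 had 2.24 within slide 1, HSPA6 2.73, HSPB1 2.08 and KLF4 1.50. HMOX1 was the 1 of 11 oxidative stress and iron genes that fell (1 adjusted over the list alone). None of 5 hypoxia and glycolysis genes passed (ADM -1.46, P4HA1 -1.25, the latter 0.570 as the mean of its probes), none of 5 cell cycle genes (AURKB -0.90, and CCNB1 not well above background on any TAG array) and none of 7 oxidative phosphorylation genes (COX7A1 0.77, ATP5A1 -0.52), and adjusted over the list alone 0 passed in each. As the mean of their probes AURKB had 0.414 and ATP5A1 0.689. F5 was the 1 of 13 coagulation and fibrinolysis genes that fell, and adjusted over the list alone 1 fell and 1 rose. Median log2 differences, with those within slide 1 in parentheses, were 0.87 (0.85) for immediate early and heat shock genes, -0.05 (-0.41) for oxidative stress, -1.02 (-0.32) for hypoxia, -0.35 (-0.26) for the cell cycle, -0.12 (-0.46) for oxidative phosphorylation and 0.18 (-0.22) for coagulation.

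Among markers of other cells in the sample ACTA1, the skeletal muscle actin, rose by 2.48 ± 0.41 (adjusted p = 0.0210), the 1 of 13 skeletal muscle genes past the test (1 adjusted over the list alone). Of its 15 other probes passing the filter, 8 had the same sign, with log2 fold changes over all its probes from -1.94 to 2.48, and the actin genes are near-identical in sequence, so the value is uncertain. The mean of its probes gave 0.30 and did not pass. GPD1 (glycerol-3-phosphate dehydrogenase) rose by 2.16 ± 0.48 as 1 of 11 adipocyte genes, and GP9 (a platelet glycoprotein) by 2.33 ± 0.60 as 1 of 3 blood genes (1 each adjusted over the list alone). ACTA1 had 2.70 within slide 1, GPD1 1.37 and GP9 1.06, and with slide as a block GPD1 and GP9 did not pass. None of 2 nerve genes (MBP 0.53, and SOX10 not well above background on any TAG array) nor the lymphatic gene CCL21 passed, over all features or adjusted over the list alone. CCL21 had 0.68, and -2.68 within slide 1 (adjusted p = 0.0301). Median log2 differences, with those within slide 1 in parentheses, were -0.25 (-0.39) for skeletal muscle, 0.02 (-0.34) for adipocytes, 0.14 (-0.27) for blood and -0.10 (-0.36) for nerve.

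The genes that rose most were often dim in Exoseal arteries. The lowest signal well above background was 9.19 to 10.9 on TAG arrays, whose 75th percentile was 19.3 to 36.4. On Exoseal arrays it was 4.44 to 12.8, with a 75th percentile of 61.0 to 151. After scaling this floor lay higher on TAG arrays, and how far it adds to the rises of dim genes was not tested. SLC7A3 (a cationic amino acid transporter) had a log2 fold change of 4.31 ± 1.04 (adjusted p = 0.0360), KRT2 (a keratin) 3.88 ± 0.86, PLG (plasminogen) 3.42 ± 0.68, TFAP2C (a transcription factor) 3.07 ± 0.71, DIS3L2 (an exoribonuclease) 3.05 ± 0.65, LNPEP (an aminopeptidase) 3.04 ± 0.44 and SLC16A1 (a monocarboxylate transporter) 2.95 ± 0.63, each above background on 1 or 2 of the 3 Exoseal arrays, with SLC7A3 and TFAP2C also on 2 of 3 TAG arrays. PDX1 (a transcription factor of the pancreas) and LPCAT4 (a phospholipid acyltransferase) were not well above background on any Exoseal array and were at least 8.38-fold and 7.69-fold higher in TAG at the scaling used. These bounds did not hold in other settings, where the fitted log2 fold changes were 1.89 and 1.65 within slide 1, 2.39 and 2.22 in the authors' table, and 0.61 and 0.54 with normexp and quantile scaling. Over all settings SLC7A3 ran from 0.60 to 5.73, KRT2 from 0.92 to 5.04, PLG from 0.56 to 4.24 and TFAP2C from 0.95 to 3.90. DIS3L2 ran from 0.56 to 3.77, LNPEP from 0.53 to 3.31 and SLC16A1 from 0.62 to 3.67. COL5A1, HSP70.2 and TEAD1 (a transcription factor of the Hippo pathway, 3.03 ± 0.71) were above background on all 6 arrays. Within slide 1 the fitted log2 fold change was 1.48 for SLC7A3, 1.56 for KRT2, 1.78 for PLG, 2.33 for COL5A1, 2.24 for HSP70.2, 1.62 for DIS3L2, 1.62 for TEAD1 and 1.50 for SLC16A1. As the mean of their probes PLG (2.70), PDX1, TEAD1 (1.06) and SLC16A1 (1.55) did not pass, but no other probe of PLG, PDX1 or SLC16A1 passed the filter. Of the 48 named genes past the threshold (27 higher, 21 lower), 18 passed with slide as a block, 4 higher (HSP70.2, HSPA6, LNPEP and ACTA1) and 14 lower (among them ACP5, CCR1, LYZ and MMP9).

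None of the 24 lists tested passed an adjusted p of 0.05 with limma's camera, and 3 had an unadjusted p under 0.05. The smallest belonged to foreign body and giant cell genes, lower in TAG (p = 0.00234, adjusted p = 0.0561, and adjusted p = 0.896 with an estimated correlation). Immediate early and heat shock genes and complement genes, both higher, had a camera adjusted p of 0.105 and 0.275, and both 0.896 with an estimated correlation. That 0.896 was the smallest adjusted p of any list in that version of camera. Many lists shared it, so it does not single these out. With slide as a block the foreign body list had a camera adjusted p of 0.00873, the only list past the threshold there, and its median within slide 1 was -1.22. Over all settings run at the preset correlation its adjusted p ran from 5.31e-05 to 0.717 with the same direction. None passed the directional test of fry (smallest adjusted p 0.0793, fibrillar collagen), and 18 passed its mixed test, which takes changes of members in either direction together and does not compare them with other genes. The test's direction differed in sign from the list's median for some lists whose members went both ways, among them skeletal muscle, interferon response and endothelial activation genes. With members not well above background in a group set at their bound, the largest shift of a list's median was 0.39, and the medians of nerve genes (0.27) and the phenotypic switch (0.06) became positive.

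**Figure D3:**
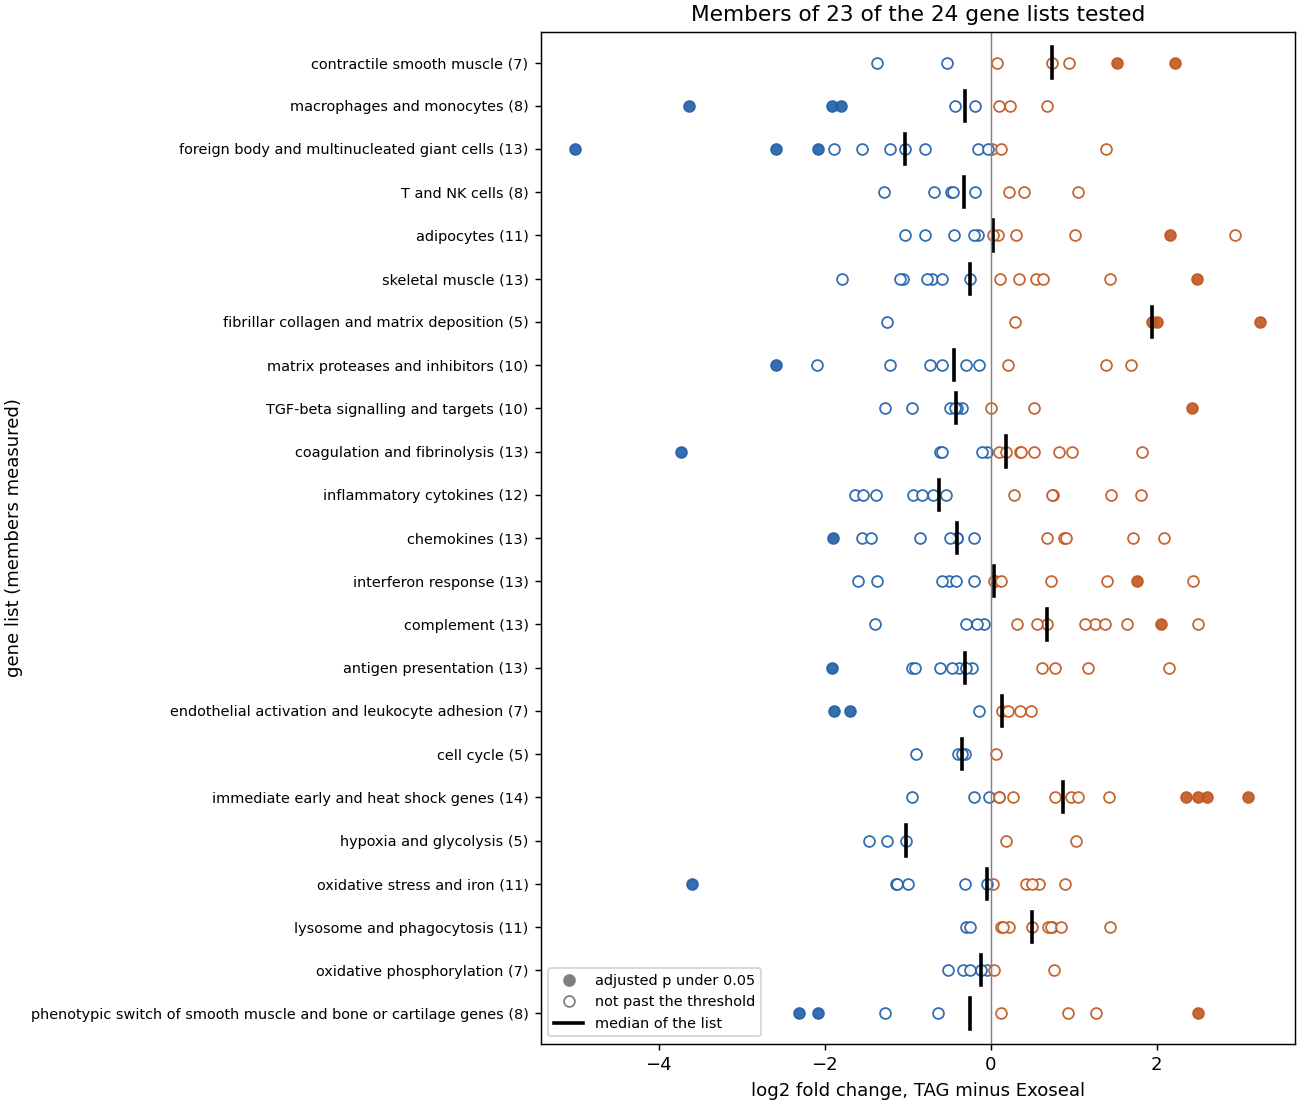
Log2 fold change of each measured member, TAG minus Exoseal (x axis), for 23 of the 24 gene lists tested (y axis, members measured in parentheses). Filled points passed an adjusted p of 0.05, open points did not, and black lines are medians. Members of most lists lie on both sides of 0, and foreign body and giant cell genes have a median of -1.03.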

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

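The percentile over detected probes and the fit on slide 1 alone were chosen after the data were examined. The 2139 calls (1374 higher, 765 lower in TAG) became 1152 (693, 459) with normexp and quantile scaling, 1105 (508, 597) with median scaling, 10634 (5597, 5037) with array weights, whose estimate did not converge, 3529 (2379, 1150) with Exoseal replicate 1 counted as TAG, and 0 with no filter (smallest adjusted p 0.0538 over more features). Lower calls alone moved to 1413 with quantile scaling and 464 with the filter on all 6 arrays, which tests fewer features. Leaving out single arrays gave 0 to 6957 calls (0 to 4231 higher, 0 to 2726 lower), with fewer samples. The replicate block gave 0 calls (smallest adjusted p 0.0513, 2 residual degrees of freedom). Deviations of same-numbered arrays from their group means had r = -0.204, 0.0717 and -0.0765, and those of other pairs ran from -0.170 to 0.210. This does not settle whether the numbers pair the samples, since the Exoseal deviations also hold the slide difference. The 6251 features at an unadjusted p under 0.05 and at least 2-fold became 1564 with normexp, 13158 with no filter, 3521 with the filter on all 6 arrays, and 4081 to 8957 without single arrays. With normexp the offset of 50 shrinks fold changes. At an unadjusted limma p under 0.05 of any fold there were 5758 features with it and 6309 without. Lists past the threshold, 0 at first, were 1 with normexp, the filter on all 6 arrays, the slide block and slide 1 alone (foreign body genes, down, in each), 2 with no filter (these and macrophages, down), 2 with the mean of probes (heat shock and fibrillar collagen, up) and 0 to 2 without single arrays (2 without TAG replicate 3, 1 without Exoseal replicate 3). All other alternatives left the counts within 1.5 times. Of the 48 named genes past the threshold, 43 passed with quantile scaling, 43 in the authors' table, 30 with median scaling, 27 with the mean of probes, 18 with the slide block, 30 with normexp, 48 without Exoseal replicate 1 and 0 without each of the other 5 arrays. Signs turned with the mean of probes for CD86 (0.0140), AURKB (0.414), P4HA1 (0.570), KIT (0.971), ATP5A1 (0.689) and PECAM1 (0.743), with array weights for CCNB1 (0.207), with normexp for CCL21 (-0.273) and RGS5 (-0.126), and with the slide block and slide 1 alone for CCL21 (-2.68) and MBP (-0.417). Without single arrays CCL21 ran from -0.307 to 2.36, KIT from -0.746 to 0.142 and MBP from -0.0282 to 1.00. CD86 alone of these had passed the threshold, and its mean takes in a probe that did not pass the filter. Unless stated, the cause was not tested for these counts and signs. Scan day as a block was not run, since all arrays were scanned on 1 day. Detected probes differed by -11673 per array by the scanner's flag and -10912 against the 99th percentile of negative controls. On TAG arrays, signal over background limits the 399 calls that were not above background there.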

Other observations

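The genes of the next 2 paragraphs, and every test below other than the splits of the arrays, were chosen after the results were seen. Outside the genes named so far, 31 named genes passed the threshold with at least a 4-fold difference and signal above background on all 6 arrays, 22 higher and 9 lower in TAG. HIF1A, the oxygen-regulated transcription factor, was higher by 2.84 on the log2 scale (adjusted p = 0.0210 in limma, 3 of 3 TAG arrays above every Exoseal array), and by 3.47 within slide 1. The transcription factor KLF15 (2.40), the lipoxygenase ALOX15 (2.09), the angiopoietin-like ANGPTL7 (2.47) and the LIM domain gene LMCD1 (2.10) were also higher. Within slide 1 KLF15 had 2.19, ALOX15 2.38, ANGPTL7 1.75 and LMCD1 1.42. TPI1 (triosephosphate isomerase, 2.66, with 4 of 4 other probes of the same sign), PYGL (liver glycogen phosphorylase, 2.17) and VDAC1 (a mitochondrial channel, 2.29) were higher, and UGP2 (UDP-glucose pyrophosphorylase, -2.64, with 4 of 4 other probes of the same sign) was lower. Within slide 1 TPI1 had 1.85, PYGL 1.29, VDAC1 2.16 and UGP2 -1.75. Another fallen gene was GP91-PHOX, the catalytic subunit of the phagocyte NADPH oxidase (-2.07, and -2.15 within slide 1). IFI30 (-2.53, and -1.53 within slide 1) and GPI (-2.64, and -1.99) were lower by their brightest probe, and the 1 other probe of each that passed the filter had the opposite sign.

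The 13 measured skeletal muscle genes differed between single arrays, by 1.32 (CKM, muscle creatine kinase) to 7.66 (MYH2, a fast myosin heavy chain) from the lowest to the highest log2 level, and did not share an order of the arrays. MYH2 lay at -3.71 on Exoseal replicate 1 and 3.94 on Exoseal replicate 2, and MYOT (myotilin) at -3.93 and 3.19. TNNI2 (fast troponin I) lay at 2.02 and -1.74 on the same 2 arrays, MYH1 (a fast myosin heavy chain) at 2.50 and 0.30, and MYH4 (a fast myosin heavy chain) at -0.69 and -0.68. Spread within and between the groups was not compared by a test.

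The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 2139 calls against at most 0 in the other splits (1 of 10 as large), and 6251 features at an unadjusted p under 0.05 with at least 2-fold against at most 2293 (1 of 10). For lists past the threshold the real split gave 0 and the others up to 4, so 10 of 10 were as large.

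Exoseal replicate 1, labelled both Exoseal and TAG and scanned with the TAG arrays, lay apart from Exoseal replicates 2 and 3. A difference between the slides as the whole cause of the calls would leave it with TAG. Its position was taken over 8957 features that separated TAG from Exoseal replicates 2 and 3. The median was 0.415 of the way from TAG (0) to them (1), and 0.397 to 0.441 on axes without 1 of the TAG arrays. TAG arrays held out in turn lay at -0.0620 to 0.116. This cannot decide the question, since it rests on 1 array with conflicting labels. That array also detected more probes (60.6%) than the TAG arrays of its slide (37.4% on average). A TAG sample with a wrong title stays open, since the correlations set this array apart from both groups. Its highest r with a TAG array was 0.855, where the lowest between TAG arrays was 0.944. With Exoseal replicates 2 and 3 it had 0.789 and 0.851, where these had 0.936 with each other. Spread between Exoseal arteries together with a slide difference stays open too. The lowest r of Exoseal replicate 1 with the other Exoseal arrays (0.789) holds both, and they cannot be told apart.

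Calls among the dimmest 40% of features were mostly higher in TAG, 746 of 1104 (67.6%). A different background on the slides and the scaling by the 75th percentile both stay open. The share was 42.1% on slide 1 alone (543 of 1290), 44.3% with quantile scaling (718 of 1621) and 75.1% without Exoseal replicate 1, but calls lower in TAG went from 358 to 747 on slide 1 and to 903 with quantile scaling, so a smaller share does not show that the higher calls came from either. The treatment stays open as an untested cause. In the brightest 20% of features 74.8% of calls were higher in TAG, 78.9% within slide 1, 62.5% with quantile scaling and 59.1% without Exoseal replicate 1.

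Of 21 measured macrophage and giant cell genes 6 fell in TAG and 15 did not pass. The 5 fixed macrophage genes above background on all 6 arrays moved apart by more than their standard errors, from LYZ at -3.64 to C1QA at 0.68. Their heterogeneity Q was 35.8, 29.0 within slide 1 and 27.6 as the mean of probes, where 4 would be the expectation for genes moving alike and independently. So the 5 did not fall alike, and another probe of LYZ had -0.91. A smaller share of macrophages of a single kind stays open, since these genes need not come from such cells alone. Lower sensitivity of the TAG arrays stays open. The median of both lists together (-0.79) lay at the 0.160 percentile of 10000 random lists matched on mean level. But the lists were pooled after their values were seen, and random lists ignore the correlation between genes. Both lists, like many others, had a camera adjusted p of 0.896 with an estimated correlation. A slide difference stays open too: the 8 members lower without Exoseal replicate 1 had a median of -2.61 against that array within slide 1, all 8 below 0, but that rests on 1 Exoseal array. A change in the state of the phagocytes between glue and device remains a hypothesis that was not tested.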
